A study of Mus musculus with 6 samples.

How the data were processed

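Cortex was profiled from mice that carry a bacterial artificial chromosome driving an EGFP-tagged ribosomal protein in S100a10-expressing cells (translating ribosome affinity purification, TRAP) and that constitutively lack p11, the protein encoded by S100a10. Per the labels, one group drank fluoxetine at 0.167 mg per ml in 1% saccharin (FLX) and the other 1% saccharin alone (VEH) for 15 to 18 days. Each group had 3 arrays, described as independent TRAP replicates, on a C57BL/6 background reached from FVB by 3 to 5 generations of backcrossing. Per the labels' protocols, ribosomes were immunoprecipitated, the bound RNA was extracted and DNase-treated, and 15 ng was amplified in 2 cycles, labelled with biotin and hybridised to Affymetrix mouse arrays in 1 colour.

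The deposited values are probe set intensities on a linear scale, normalized with GCRMA per the submitters' processing notes, whose version and settings are not given in the sources used here. In its standard form GCRMA corrects background by probe sequence, applies quantile normalization and summarises the probes of a set. The linear scale was read from the values themselves, which were above 0 in all 6 arrays and ran from 1.60 to 76587. Per the labels the replicates were averaged by the submitters for their own comparison, whereas the table analysed here holds 1 column per array.

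Of 45101 probe sets, 64 are controls and stayed out of the tests. The platform annotation names 1 gene for 34945 of the other 45037 probe sets and several genes for 932, and 9160 are not named here. The gene identifiers changed 0 symbols when they were looked up in a newer gene table. Genes are named only from probe sets with 1 symbol. Probe sets ending in _x_at or _s_at can match several transcripts. The submitters advise leaving out values below 50 and keeping only a list of probe sets from their paper, because the transgene also labels some non-neuronal cells. That list was not used here. Probe sets were tested where the mean of at least 1 group was 50 or more, which left 22200 probe sets, of which 20192 had 1 symbol and stood for 12214 genes.

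FLX was compared with VEH by limma 3.58.1 in R 4.3.3 on log2 of the normalized value, with no pseudocount, treatment as the only term, default empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment over all probe sets tested at a threshold of 0.05. A descriptive count of probe sets at 1.5-fold or more with an unadjusted p under 0.05 was made in each direction. Each gene list was tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, taking the probe set with the highest mean for each gene and adjusting over all lists tested. There were 42 lists with 1001 genes, of which 774 were tested. The lists of red blood cell genes and of sex-linked genes had 3 tested members each, below the minimum of 5, so 40 lists were tested. An adjusted p given with a list comes from camera with the preset correlation unless another test is named. A log2 difference is FLX minus VEH and an error given with a mean is the SD over 3 arrays. Single measures were compared by an exact two-sided permutation test, which with 3 arrays against 3 cannot go below p = 0.1. RNA integrity was also compared within pairs by an exact test that turns the sign of each difference, added after seeing the data, which with 3 pairs cannot go below p = 0.25. Figures were drawn with matplotlib 3.10.9.

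The groups, the test, the filter, the lists, the rule for naming genes and most alternatives were chosen before the data were examined. Under that rule S100a10 came first. In each direction the 12 genes were named that had the smallest unadjusted p among those with at least 1.5-fold difference and no overlap between the groups, since none passed the threshold. The rule gave such genes their most changed probe set, but the probe set with the smallest unadjusted p was used, which is another one for Socs3 alone. The rule also named the 2 members of each list with the smallest unadjusted p and all detected serotonin receptors, by their brightest probe set. For several lists only 1 of the 2 members is given below. Genes named outside the rule are marked as chosen after their values were seen.

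FLX and VEH arrays share replicate numbers 1 to 3. The labels do not say what a number stands for. Deviations from the group means correlated across tested probe sets at r = 0.70, 0.84 and 0.87 between arrays with the same number, which is above the limit of 0.1 set for calling the arrays paired. The VEH replicate 1 array correlated better with the FLX replicate 2 array, at r = 0.76, and FLX replicate 1 with VEH replicate 2 reached 0.64. These unlike numbers pass the limit too, so it cannot establish pairs 1 and 2. The numbers pair the arrays mainly through replicate 3. A fit with the replicate number as a block was planned as an alternative. Data were simulated with the replicate differences of these arrays and independent noise of limma's moderated within-pair spread. There limma without the block called 0 of 100 probe sets changed by log2 1 and 0 of 100 changed by log2 2. With the block it called 95 and 100 of them, with 25 false calls in all 22200 probe sets. Such noise is more uniform than real spread, so these counts do not give the power of the real test. In the real blocked fit Wfs1, at 1.11 (SE 0.16), had an adjusted p of 0.623. A list shifted by 0.5 was called by camera and 0 of the 39 other lists were. That list simulation had independent noise, without replicate differences or correlation between genes. It therefore does not show how often camera calls unchanged lists in the real arrays.

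Other alternatives were different filters, a log offset of 16, quantile normalization, median centring, array weights, each array left out in turn, 1 probe set per gene, other variance priors and an ordinary test without moderation. Fits without both replicate 3 arrays and blocked fits without a pair were added after seeing the data. No array repeated another, with at most 725 of the 45101 values equal between any 2 arrays. The number of arrays limits the precision throughout, and limma's p-values measure the spread between these TRAP replicates. Camera's p-values with the preset correlation compare list members with other genes as if genes were nearly independent.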

Results

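Gene expression was measured in ribosome-bound RNA from S100a10-expressing cells of the cortex in mice lacking p11, with 3 arrays from fluoxetine-treated mice (FLX) and 3 from vehicle-treated mice (VEH). The comparison asks what treatment with fluoxetine, a selective serotonin reuptake inhibitor, does to the translated mRNA of these cells when p11 is absent. Median values over all probe sets were 38.5 to 41.9, and 21158 to 21682 probe sets per array had a value of 50 or more. Among replicates 1 and 2 of both groups the arrays correlated at r = 0.987 to 0.995. The replicate 3 arrays of both groups stood apart, with r = 0.867 to 0.916 to the other arrays and 0.973 to each other. The first principal component, which separated replicate 3 from the rest, held 84.6% of the variance and the next held 8.77%. That second component set FLX replicate 3 (42.9) against VEH replicate 3 (-41.6), with the other arrays between -9.57 and 5.88.

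S100a10, the gene deleted in these mice, was represented by 3 probe sets. The brightest, of the x_at type, gave 2222, 2037 and 349 in FLX replicates 1 to 3, and 3111, 2248 and 643 in VEH replicates 1 to 3. The next lay between 34.0 and 49.4 over the 6 arrays, and the dimmest between 4.98 and 8.22, both under the minimum of 50. No wild-type array was analysed here, and the position of these probes relative to the deleted part is not given in the sources used here, so the values check nothing about the genotype. The x_at probe set may match other transcripts, and it had a log2 difference of -0.50 (SE 0.92, 3 arrays per group).

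Genes for GABA and glycine receptors, the inhibitory receptors of the brain, listed with their scaffold gephyrin, rose as a group in FLX arrays, with a median log2 difference of 0.47 over 13 members, all of them positive (3 arrays per group). Astrocyte markers rose by a median of 0.31, and genes for potassium and HCN channels, for neuromodulator receptors and for synaptic vesicle release by medians of 0.22, 0.20 and 0.16. Ribosomal protein genes fell, with a median of -0.23 over 41 members, as did activity-regulated early genes at -0.26, glucocorticoid-responsive genes at -0.13 and oxidative phosphorylation genes at -0.04. These 9 of 40 lists, 5 higher and 4 lower, passed camera with the preset correlation of 0.01. With an estimated correlation the adjusted p was 0.791 for each of them, and with fry 0.920. In the order given, the estimated correlation was 0.43, 0.26, 0.26, 0.29 and 0.007 for the 5 higher lists. For the 4 lower lists it was 0.53, 0.27, -0.04 and 0.08. The values 0.007 and -0.04 lie below the preset 0.01, so correlation between genes does not account for every lost call. With an estimated correlation camera also rests on the few residual degrees of freedom of 6 arrays, so a lost call there decides little. No single gene passed limma's threshold. The mean difference between 3′ and 5′ probe sets of Gapdh and Actb, which rises as RNA integrity falls, was also lower in the FLX array in 3 of 3 pairs.

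**Figure D1:**
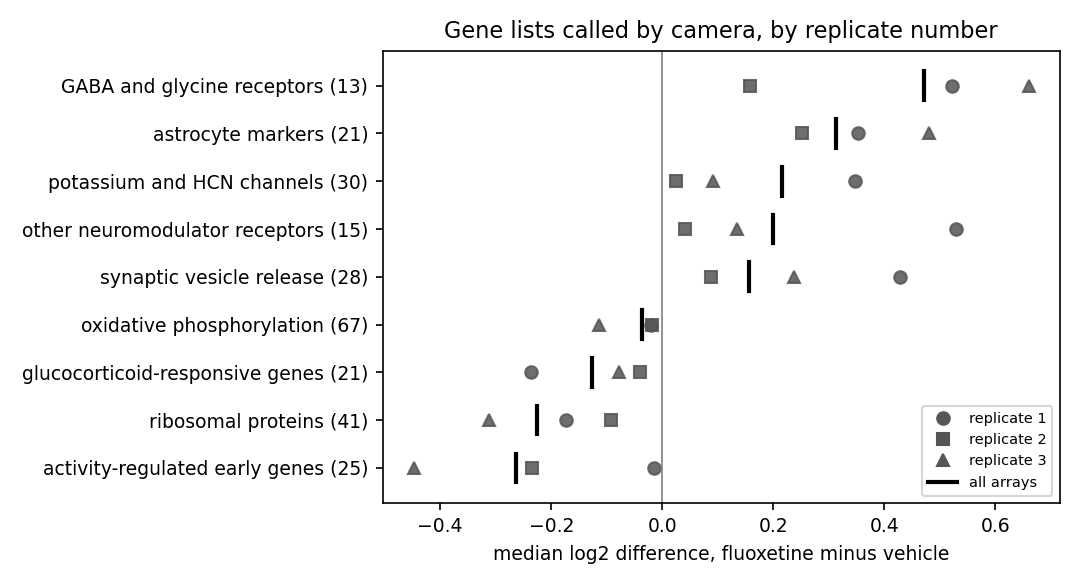
Median log2 difference (x axis, FLX minus VEH) of the 9 lists called by camera (y axis, with the number of members), given for each replicate number as a symbol and for all 6 arrays as a bar. The median of the 13 genes in the GABA and glycine receptor list was 0.52, 0.16 and 0.66 in replicates 1, 2 and 3, and that of the 41 ribosomal protein genes was -0.17, -0.09 and -0.31.

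Receptor and channel genes formed most of the lists that rose. Within the GABA and glycine receptor list (adjusted p = 1.01e-06), Glra2, a glycine receptor alpha subunit, had a mean of 304 ± 57.6 in FLX and 177 ± 49.0 in VEH arrays. Gabrg1, a gamma subunit of the GABA-A receptor, had 130 ± 18.4 and 81.0 ± 23.5. Glra3, chosen after its values were seen, had the largest difference of the list at 1.28 (SE 0.51). Of the 13 members, 11 were higher in all 3 pairs of equal replicate number, 0 passed when adjusted over the list alone, and 2, Gabrg1 and Glra3, did so with the replicate block. In replicate 3, compared with replicates 1 and 2, the list had medians of -0.41 in FLX and -1.28 in VEH arrays, with 10 and 12 of the 13 genes lower. Without the VEH replicate 3 array the median of the list was 0.15 (adjusted p = 0.0433), the least favourable of the single arrays left out, and without both replicate 3 arrays it was 0.33 (adjusted p = 1.36e-06).

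Of 30 potassium and HCN channel genes (adjusted p = 0.0178), 24 had a positive difference, and Kcnd3, a subunit of A-type potassium channels, had 650 ± 96.4 against 468 ± 180.4. Of 15 neuromodulator receptor genes (adjusted p = 0.0237), 11 were positive. Npy2r, a neuropeptide Y receptor, had a log2 difference of 0.68 (SE 0.42), and Cnr1, the cannabinoid receptor of neurons, had 2649 ± 694 against 1866 ± 533. Of 28 genes for synaptic vesicle release (adjusted p = 0.0360), 22 were positive, among them Rab3c at 0.48 and Nrxn2 at 0.42. In each of these 3 lists 0 members passed when adjusted over the list alone. With the replicate block 1 member of the neuromodulator receptor list did, which was Npy2r. Replicate 3 differed from replicates 1 and 2 by medians of -0.42 and -0.49 (FLX and VEH) for the channel list, -0.66 and -0.72 for the neuromodulator receptors and 0.05 and 0.35 for the vesicle list. All 3 lists lost their call without the VEH replicate 1 array, without the FLX replicate 1 array and without the FLX replicate 2 array, and the channel and receptor lists also without the VEH replicate 3 array. The receptor list also lost its call with no filter, and the vesicle list with the mean of all probe sets of a gene. With 1 array left out the adjusted p reached 0.446 for the channels, 0.424 for the receptors and 0.810 for the vesicle list. The medians then ran from 0.04 to 0.38, from 0.07 to 0.45 and from 0.10 to 0.24.

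Astrocyte markers (adjusted p = 0.00443) had positive differences in 16 of 21 genes. Aqp4, the water channel of astrocyte endfeet, had 387 ± 154 in FLX and 188 ± 119 in VEH arrays, and Bmpr1b had 80.4 ± 10.7 and 45.0 ± 26.1. Gfap, the astrocyte intermediate filament, chosen after its values were seen, had 763 ± 679 and 272 ± 240.1. Its values were 370, 372 and 1546 in FLX replicates 1 to 3 against 109, 159 and 547 in VEH replicates 1 to 3. None of the 21 genes (0) passed when adjusted over the list alone, and 2 did with the replicate block, Gfap and Aqp4. The median of the list in replicate 3, compared with replicates 1 and 2, was 0.09 in FLX and -0.70 in VEH arrays. The list lost its call without the FLX replicate 2 array, without the VEH replicate 1 array and without the VEH replicate 3 array, with an adjusted p of up to 0.715 and medians that stayed at 0.18 or more.

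**Figure D2:**
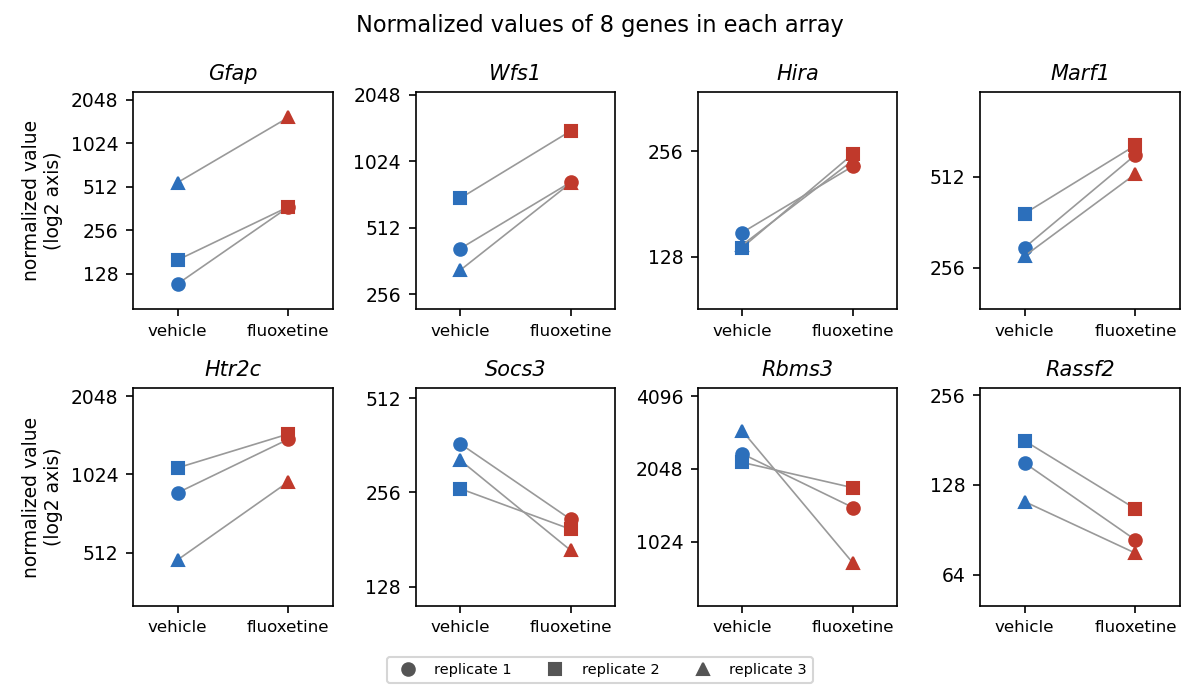
Normalized values (y axis, log2 scale) of 8 genes in VEH and FLX arrays (x axis), with symbols for the replicate number and lines joining arrays of the same number. Gfap ran from 109 to 547 in VEH and from 370 to 1546 in FLX arrays, and Rbms3 had means of 2496 in VEH and 1320 in FLX arrays.

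Activity-regulated early genes, which are induced within minutes to hours of neuronal firing, had negative differences in 20 of 25 members (adjusted p = 0.00375). Ier2 had 491 ± 56.8 in FLX and 852 ± 283 in VEH arrays and Gadd45b had 777 ± 63.0 and 1163 ± 296. In replicate 3 the median of these genes was 0.73 higher in FLX and 0.77 higher in VEH arrays than in replicates 1 and 2. The median of the list was -0.02 in replicate 1, -0.23 in replicate 2 and -0.45 in replicate 3. Without the VEH replicate 3 array the median was 0.08 (adjusted p = 0.968), where camera's direction reversed as well. Without the FLX replicate 2 array the call was lost (adjusted p = 0.548) and the median was 0.10, while camera's direction stayed lower. Glucocorticoid-responsive genes were negative in 18 of 21 (adjusted p = 0.0139). Ddit4, a stress-induced inhibitor of mTOR signalling, had 1379 ± 1256 against 2586 ± 445, lower in replicates 1 and 2 (-1.72 and -2.54) and higher in replicate 3 (0.27). The other member named by the rule, Plin4, had a difference of -0.22. This list lay near 0 in replicate 3 relative to the others (0.00 in FLX and -0.15 in VEH arrays), and its call was lost without the VEH replicate 1 array and without the VEH replicate 3 array (adjusted p up to 0.150). With 1 array left out its median ran from -0.14 to -0.02, the latter without the VEH replicate 1 array. In both lists 0 members passed when adjusted over the list alone, with or without the replicate block.

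Ribosomal protein genes had negative differences in 34 of 41 members (adjusted p = 3.61e-10), and 25 of them were lower in all 3 pairs against 0 higher in all 3. Rpl37 had 285 ± 68.0 in FLX and 393 ± 64.6 in VEH arrays, and Rps10 had 13572 ± 3079.5 and 18079 ± 934. Replicate 3 medians, compared with replicates 1 and 2, were -0.43 in FLX and -0.30 in VEH arrays, with 37 and 32 of the 41 genes lower. The list stayed past the threshold with any single array left out, at medians from -0.28 to -0.03, the latter without the FLX replicate 3 array (adjusted p = 0.0249), and without both replicate 3 arrays its median was -0.13 (adjusted p = 1.44e-04). Of 67 genes for oxidative phosphorylation, 43 were negative (adjusted p = 0.0116), among them Atp5e at -0.58 (SE 0.31) and Ndufa7 at -0.42 (SE 0.25). With the replicate block this list had an adjusted p of 0.0527, and without both replicate 3 arrays 0.585, so its call was lost in both. It was also lost without the FLX replicate 3 array, where the median was 0.01 (adjusted p = 0.402), without the VEH replicate 1 array (-0.00, adjusted p = 0.127) and without the VEH replicate 3 array, where the median was further from 0 (-0.09, adjusted p = 0.150). Its replicate 3 medians were -0.15 in FLX and 0.03 in VEH arrays. In both lists 0 members passed when adjusted over the list alone.

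Serotonin receptor genes, the family on which the transmitter raised by fluoxetine acts, did not pass as a list (median 0.19 over 7 detected members, adjusted p = 0.168). The list passed without the FLX replicate 3 array (median 0.27, adjusted p = 0.0145) and without the VEH replicate 2 array (0.16, adjusted p = 0.0414), and its median was lowest, 0.07, without the VEH replicate 3 array. Htr2c had 1273 ± 275 in FLX and 811 ± 307 in VEH arrays, with log2 differences of 0.69, 0.43 and 1.00 in the 3 pairs. It was the 1 member that passed when adjusted over the list alone with the replicate block, and 0 passed without it. Htr1a had a log2 difference of 0.46 (SE 0.37), Htr3a 0.25, Htr5a 0.19, Htr7 0.06, Htr1b -0.07 and Htr1f -0.11. In replicate 3, compared with replicates 1 and 2, the list had medians of -0.35 in FLX and -0.77 in VEH arrays, with 6 and 5 of the 7 genes lower. The list of p11 partners, whose 13 genes include S100a10 itself (adjusted p = 0.855), had Bad at -0.34 and Trpv6 at 0.23 as the members with the smallest p.

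Markers of other cortical cell types separated the replicate numbers more than the treatments. Leptomeningeal and fibroblast markers, the genes of the membranes around the brain, were lower in replicate 3 than in replicates 1 and 2 in 18 of 18 genes in both groups, with medians of -3.87 in FLX and -3.46 in VEH arrays. Pericyte and smooth muscle markers were lower by medians of -3.31 and -3.10, interferon response genes by -2.12 and -2.25, lysosome genes by -1.73 and -2.13, microglia and macrophage markers by -1.02 and -1.87, and endothelial markers by -0.97 and -1.67. Oligodendrocyte markers were higher by medians of 1.45 and 1.15, layer 5b subcerebral markers by 1.04 and 0.85 and interneuron markers by 0.93 and 0.69. Between treatments, none of these lists passed without the replicate block. Leptomeningeal markers had a median of -0.40 and an adjusted p of 0.0974, and the direction depended on which array was left out. Without 1 replicate 3 array, that of the other group is unmatched, so the replicate 3 difference enters the comparison. The leptomeningeal median was 0.95 without the FLX replicate 3 array (adjusted p = 0.00277) and -1.63 without the VEH replicate 3 array (adjusted p = 7.75e-04). With the block, 16 lists passed, 10 higher and 6 lower, and adjusted p = 0.678 with an estimated correlation for each list that had passed without the block. Among those that passed with the block alone, leptomeningeal markers had an adjusted p of 8.52e-07, with Foxd1 at -0.79 and Igf2 at -0.85, and pericyte and smooth muscle markers had 2.41e-04, with Acta2 at -0.73 and Pdgfrb at -0.73. Interferon response genes had 0.00210 (median -0.21, Oas1a -0.80 and Rsad2 0.26). Lysosome genes had 0.00525 (median 0.19, Atp6v1h 0.45 and Npc1 0.82) and interneuron markers 0.00779 (median 0.20, Reln 0.55 and Slc32a1 0.50). The adjusted p of these 5 lists with the block and an estimated correlation was 0.678, or 0.754 for the interneuron markers. The medians in pairs 1, 2 and 3 were -0.64, 0.11 and -0.60 for the leptomeningeal markers, with 5 of 18 genes lower in all 3 pairs, and -0.86, 0.02 and -0.45 for the pericyte and smooth muscle markers, with 2 of 7. Both lists passed with the block when any pair was left out. The lysosome list did not without pair 3 (adjusted p = 0.0557), nor did the interneuron markers (0.709) and the interferon response genes (0.445) without pair 1. Without the block and with 1 array left out, lysosome genes passed without FLX replicate 3 (median 0.74) and VEH replicate 2 (0.58). Their median turned to -0.47 without VEH replicate 3 (adjusted p = 0.0581) and to -0.19 without FLX replicate 2. Interneuron markers passed without FLX replicates 1 and 2 (0.39 and 0.53) and VEH replicates 2 and 3 (0.26 and 0.53), each left out in turn. Without FLX replicate 3 the interneuron median was -0.15. Interferon response genes passed lower without FLX replicate 1, FLX replicate 2 and VEH replicate 3 (-0.40, -0.62 and -1.03) and higher without FLX replicate 3 (0.47). Leptomeningeal markers also passed lower without FLX replicates 1 and 2, each left out in turn (-0.89 and -1.39). Pericyte and smooth muscle markers passed with no single array left out. Their median was 0.60 without FLX replicate 3, -0.09 without VEH replicate 1 and -1.55 without VEH replicate 3. With the block 2 of these genes passed when adjusted over the list alone.

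**Figure D3:**
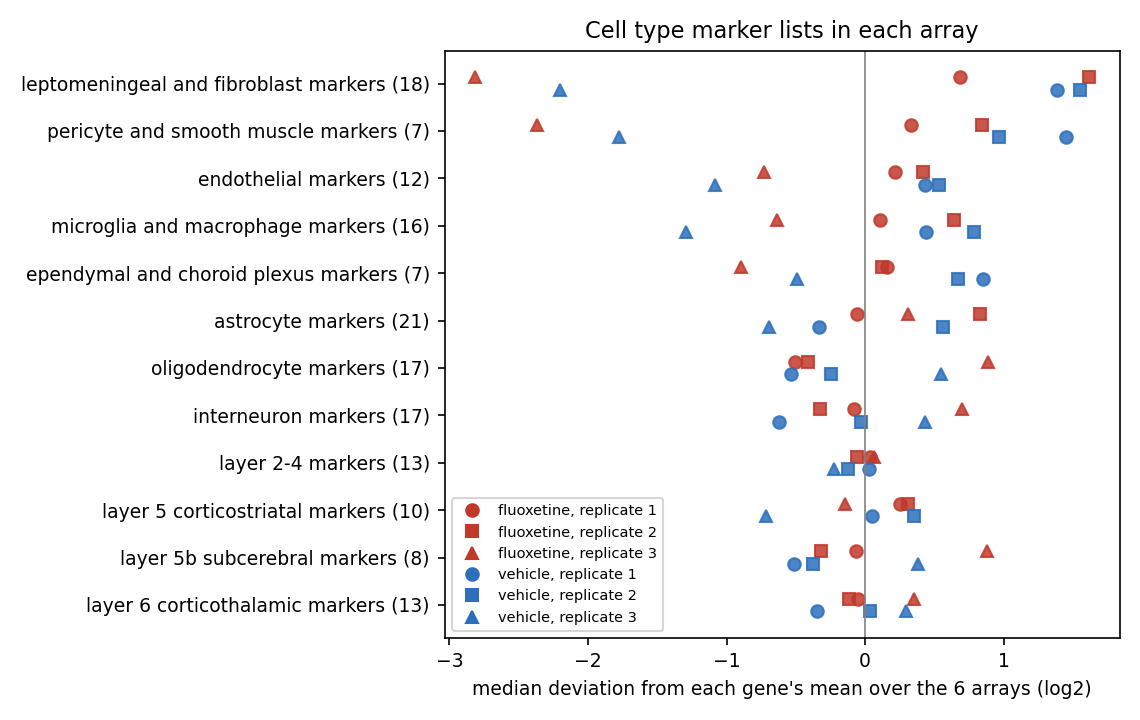
Median log2 deviation (x axis) of the cell type marker lists (y axis, with the number of members) in each of the 6 arrays, from each gene's mean over all arrays, with colour for treatment and symbol shape for the replicate number. Leptomeningeal and fibroblast markers lay at -2.81 in FLX and -2.20 in VEH replicate 3, and between 0.68 and 1.62 in the other arrays.

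Markers of cortical layers and of striatal, hippocampal and thalamic neurons did not pass with or without the block. The medians were 0.14 for layer 5 corticostriatal markers (Sema3e at 1.21 with an SE of 0.87, Plcxd2 at 0.17), 0.20 for layer 5b subcerebral markers (Crym at 0.43, Slco2a1 at -0.31), 0.15 for layer 6 corticothalamic markers (Sla at 0.31) and 0.10 for layer 2-4 markers (Lhx2 and Scnn1a both at 0.40). Adjusted p was 0.670, 0.855, 0.855 and 0.281 for these lists. Striatal neuron markers had a median of 0.22 (adjusted p = 0.327), with Ido1 at 0.51 and Drd1 at 0.26, and hippocampal and thalamic neuron markers 0.02 (adjusted p = 0.855), with Wfs1 at 1.11 and Prox1 at -0.22. Wfs1 was the 1 member of that list that passed when adjusted over the list alone with the replicate block. Oligodendrocyte markers had a median of 0.09 (Mag at 0.37) and precursor markers 0.16 (Gpr17 at 0.31). Microglia and macrophage markers had 0.09 (Cd68 at 0.61, SE 0.61) and endothelial markers -0.18 (Slco1c1 at 0.80, SE 0.86, but Eng at -0.18). In pairs 1, 2 and 3 Cd68 was at 0.18, -0.36 and 2.01 and Slco1c1 at -0.51, 0.32 and 2.58. None of these lists passed with all arrays. Leaving out 1 array changed the call of 3 of these lists. Oligodendrocyte markers passed lower without FLX replicate 3 (-0.46), endothelial markers without FLX replicate 2 (-0.48) and VEH replicate 3 (-0.45), and microglia and macrophage markers higher without FLX replicate 3 (0.44) and VEH replicate 2 (0.53) but lower without VEH replicate 3 (-0.55). Ependymal and choroid plexus markers had a median of -0.25 (adjusted p = 0.291), where Ttr, the transthyretin gene, had 94.5 ± 39.9 against 152 ± 64.4 and a log2 difference of -0.69 in each of the 3 pairs. That list passed without VEH replicate 3 (median -0.68, adjusted p = 0.0433). With the block 1 of its members passed when adjusted over the list alone.

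Among the other lists, cAMP and cGMP signalling genes had a median of 0.17 with 29 of 36 members positive. Rgs7 was at 0.39 and Pde1c at 0.78, the latter at 0.34, -0.11 and 2.10 in pairs 1, 2 and 3. The adjusted p of the list was 0.168, and 0.0424 with the replicate block. Neuropeptide genes had a median of 0.20 (Nts at 0.80, Scg3 at 0.59), with an adjusted p of 0.349, and 0.0188 with the block. Glycolysis genes had a median of 0.19 with 14 of 17 positive (Pfkm at 0.49, Pfkp at 0.42), with an adjusted p of 0.0727, and 0.0424 with the block. With the block and an estimated correlation these 3 lists had an adjusted p of 0.678, 0.754 and 0.678. Without pair 1 none of the 3 passed with the block (0.532 for signalling and glycolysis, 0.763 for neuropeptides), nor did glycolysis without pair 2 (0.254). Without the block, signalling genes passed without VEH replicate 3 (adjusted p = 0.0346), and glycolysis without that array (0.00708) and without FLX replicate 1 (0.0396). Neuropeptides passed without FLX replicate 3 (0.00122, median 0.61) and VEH replicate 2 (4.71e-04, median 0.53). The neuropeptide median was -0.11 without VEH replicate 3 and 0.06 without FLX replicate 1. Without FLX replicate 3 the signalling and glycolysis medians were 0.01 and 0.05. Neurotrophic factors and receptors (median 0.05, Nrg1 at 0.65) did not pass with or without the block. The same held for glutamate receptors (0.04, Grm5 at 0.58 but -0.72 in its other tested probe set). Sodium and calcium channels (0.15, Cacng2 at -0.29) and postsynaptic scaffolds (0.09, Homer3 at -0.43 but Lrrtm2 at 0.31) did not pass either. Axon guidance and cytoskeleton genes (0.09, Sema5a at 0.43) and circadian clock genes (0.13, Csnk1e at 0.57) also did not pass. Nor did genes reported to vary between inbred strains (-0.05, Wdfy1 at -0.51, with -1.95, -0.27 and 0.69 in pairs 1, 2 and 3). Without both replicate 3 arrays, 4 of these lists passed, glutamate receptors (median 0.24, adjusted p = 4.33e-04), sodium and calcium channels (0.22, adjusted p = 2.85e-04), axon guidance and cytoskeleton genes (0.14, adjusted p = 9.92e-05) and postsynaptic scaffolds (0.12, adjusted p = 0.0229). With an estimated correlation these had an adjusted p of 0.729. Without the FLX replicate 3 array glutamate receptors, sodium and calcium channels, axon guidance genes and neurotrophic factors passed (adjusted p = 0.00122, 1.07e-04, 0.00122 and 0.00311), as did axon guidance genes (0.0486) and neurotrophic factors (0.0140) without the VEH replicate 2 array. In 5 lists camera gave a lower direction while the median and the mean were above 0, and none of them passed. They were p11 partners (median 0.03), cholesterol synthesis (0.01, Nsdhl at 0.32 but Insig1 at -0.36) and heat shock and unfolded protein response (0.11, Trib3 at -0.58). The others were SWI/SNF and histone deacetylases (0.00, Hdac2 at 0.29) and oligodendrocyte markers. Besides Grm5, 6 members named from the lists had another tested probe set of opposite sign, Slc32a1 (-0.16), Csnk1e (-0.11), Rab3c (-0.08), Fech (-0.02), Plcxd2 (-0.01) and Slco2a1 (0.03).

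The genes named for a higher level in FLX arrays, none of them past the threshold, included Wfs1, an endoplasmic reticulum membrane protein, at 1013 ± 337 against 477 ± 192 (log2 difference 1.11, SE 0.37). Hira, a histone chaperone, had 241 ± 9.68 against 141 ± 7.55, Marf1, an RNA-binding protein, had 592 ± 64.2 against 322 ± 57.1, and Trhr, the receptor for thyrotropin-releasing hormone, had 111 ± 22.3 against 60.3 ± 8.52. The others were Anp32a at 0.89, Ankrd42 at 0.74, Dnah1, an axonemal dynein, and Tmem40 both at 0.71, Tpm3, a tropomyosin, at 0.69, Cotl1, an actin-binding protein, at 0.68, Slc25a44 at 0.66 and Homer2, a postsynaptic scaffold, at 0.64. Of these 12 genes, 7 had further tested probe sets, 17 in all, and 17 of these were under 1.5-fold or of opposite sign. The other probe set of Hira was at -0.00 and those of Anp32a at 0.32 and 0.18, while those of Hira, Cotl1, Tpm3 and Homer2 included at least 1 of opposite sign.

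Genes named for a lower level, again none past the threshold, included Socs3, an inhibitor of cytokine signalling, at 191 ± 21.7 against 318 ± 51.9 (log2 difference -0.73, SE 0.22), with its other probe set at -0.74. Rbms3, an RNA-binding protein, had 1320 ± 446 against 2496 ± 399.7, Mxd4, a MAX-binding repressor, had 2932 ± 789.5 against 5042 ± 1105, and Rassf2 had means of 88.6 and 148 (log2 difference -0.73, SE 0.26). Uqcr10, a subunit of respiratory complex III, was at -0.65, -0.64 and -0.63 in its 3 probe sets. The others were Lrrc18 at -0.96, Ccdc68 and the chromatin protein gene Hmgb2 both at -0.83, Nfic, a nuclear factor I gene, at -0.75, Jcad at -0.72, the calcium-binding protein gene S100a9 at -0.69 and Cacna2d4, a calcium channel subunit, at -0.60. Lrrc18, Ccdc68, Hmgb2 and Cacna2d4 had FLX means of 26.8, 34.4, 35.5 and 33.0, under the minimum of 50. Their VEH means of 51.7, 62.5, 60.6 and 50.2 were not far above it. The brighter probe set of Hmgb2 was at -0.32. Of these 12 genes, 9 had further tested probe sets, and in 2 of them, Socs3 and Uqcr10, all of these were lower by 1.5-fold or more. The other probe sets of Rbms3 were at -0.23, -0.22 and -0.18 and those of Mxd4 at -0.38 and -0.50, and that of Jcad had the opposite sign, at 0.06.

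Over all 22200 probe sets limma called 0 changed (smallest adjusted p 1.000), with 40 higher and 43 lower at an unadjusted p under 0.05, and an ordinary test without moderation called 0 as well. At 1.5-fold and an unadjusted p under 0.05 there were 29 higher and 32 lower probe sets. With the replicate block limma again called 0 (smallest adjusted p 0.574), with 874 higher and 890 lower at an unadjusted p under 0.05 and 275 higher and 402 lower at 1.5-fold. Without both replicate 3 arrays it called 0 (smallest adjusted p 0.579), with 538 higher and 810 lower, and 125 higher and 245 lower at 1.5-fold. The groups did not overlap in 565 probe sets higher and 397 lower in FLX arrays, 4.33% of those tested, where chance gives 10% if the pairing is left aside. By pairs, 4341 probe sets were higher and 3016 lower in all 3, or 33.1%, where chance gives 25%. The median standard error of a log2 difference was 0.31, or 0.18 with the block, against a median absolute difference of 0.16. The difference between 3′ and 5′ probe sets of Gapdh and Actb, which rises as RNA integrity falls, was 2.12 ± 0.069 in FLX and 2.23 ± 0.080 in VEH arrays (exact permutation p = 0.3). Within pairs 1, 2 and 3 the FLX minus VEH difference of this measure was -0.126, -0.0962 and -0.116, with a mean of -0.113 ± 0.015 (exact paired permutation p = 0.25, the smallest that 3 pairs can give). The difference between 3′ and middle probe sets was -0.102 in FLX relative to VEH arrays (exact permutation p = 0.1, the smallest that 3 against 3 can give). For Actb alone that measure was lower in every FLX than in any VEH array. Of the lists too short for a test, the sex-linked genes Eif2s3y, Kdm5d and Uty had log2 differences of 0.08, 0.20 and -0.24, and the red blood cell genes Fech and Bpgm 0.11 and 0.07.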

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

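Alternatives without both replicate 3 arrays, blocked fits without a pair or with another list test, and leaving out arrays for RNA quality were chosen after seeing the data. limma called 0 probe sets under every alternative chosen beforehand, but with the replicate block 67 without pair 2 and 1 without pair 3, fits with 1 residual degree of freedom that rest on limma's pooled spread. The 61 probe sets at 1.5-fold and unadjusted p under 0.05 became 132 with no filter, 677 with the replicate block, 1362 with array weights, 28 with 1 probe set per gene (fewer are tested), 31 by the ordinary test, 6 at 2-fold (a stricter count) and 370 without both replicate 3 arrays. Blocked fits without pair 1, 2 or 3 gave 1394, 2010 and 452. Array weights did not converge and gave FLX replicate 1 a weight of 133, so those counts rest mostly on 1 array. There early genes (0.10), oxidative phosphorylation genes (0.017) and astrocyte markers (-0.29) reversed and lost their call, and microglia markers reversed and passed (-0.48), as they did with the block without pair 3 (-0.17). Leaving out 1 array gave 46 to 182, beyond 1.5 times the count without FLX replicate 2 (95), VEH replicate 2 (108) or VEH replicate 3 (182). The 9 lists called became 14 with no filter, 16 with the block, 17 with array weights, 19 without both replicate 3 arrays, and 16 and 21 with the block without pair 2 or pair 3. With an estimated correlation or fry 0 were called, with all arrays, with the block, and (estimated correlation) without both replicate 3 arrays. Leaving out 1 array gave 3 to 19, with 19 without FLX replicate 3, 3 without VEH replicate 1 and 16 without VEH replicate 2. Without FLX replicate 3 interferon genes and leptomeningeal markers reversed and passed (medians with 1 array left out -1.03 to 0.47 and -1.63 to 0.95), and without VEH replicate 3 microglia markers did (-0.55 to 0.53) and early genes reversed and lost their call (-0.61 to 0.10). Leaving out any 1 array changes the share of replicate 3 in 1 group. Those unblocked fits therefore take in part of the replicate 3 difference. Where no construction is named, the cause was not tested. GABA and glycine receptors and ribosomal proteins were called in 17 of 19 settings chosen beforehand, all but the estimated correlation and fry. The block changed the call of the 1 list lost and the 8 gained and no other call. Of up to 111 named probe sets compared, 0 gained or lost a call except 6 gained with the block without pair 2. Their sign changed for 0 to 12 with 1 array left out, 13 with array weights, 10 without both replicate 3 arrays, up to 10 with the block without a pair, and 0 under other scalings. The 3′ to 5′ difference of Gapdh and Actb, lower in FLX arrays by -0.113, ran from -0.152 to -0.066 with 1 array left out. Another scaling moved the median log2 difference of all tested probe sets from 0.04 to 0.02. Values near the array's background limit what low probe sets can show.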

Other observations

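The tests of scaling, of RNA degradation and integrity, of cell type shares in replicate 3, of the replicate 3 profile and of single arrays were chosen after the results were seen, as were the genes in this part and the split and spread of the astrocyte markers. With the replicate block, Gfap had the smallest p of the genes at least 1.5-fold higher in FLX arrays. All 3 tested Gfap probe sets had positive differences (1.5, 1.32 and 0.62), and Fabp7, a fatty acid binding protein of radial glia and astrocytes, had 1642 ± 1203 in FLX and 696 ± 423 in VEH arrays. Slc15a2, a peptide transporter, had 87.4 ± 22.9 and 46.4 ± 17.4. On the lower side Atp7a, a copper transporter, had 43.0 ± 26.8 and 104 ± 37.2, a log2 difference of -1.37. None passed limma's threshold with the block, where the smallest adjusted p was 0.574.

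Replicate 3 arrays differed from replicates 1 and 2 in many genes in the same way in both treatments. Among 22200 tested probe sets 1255 were higher and 3254 lower by 2-fold or more in both groups. Ptgfr, a prostaglandin receptor, was at -5.52 in FLX and -5.50 in VEH arrays, and Ogn, which encodes osteoglycin, at -4.97 and -4.78. On the higher side Phgdh, an enzyme of serine synthesis, was at 4.76 and 3.08, Bcas1, an oligodendrocyte gene, at 3.12 and 2.69, and the complexin genes Cplx2 at 2.69 and 2.65 and Cplx3 at 3.05 and 2.49. Spike-in controls for hybridisation were brighter in VEH replicate 3 alone (1.43 above the mean of all arrays).

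The 18 leptomeningeal markers were lower in replicate 3 of both treatments. A scaling factor per array would move all probe sets one way, and is argued against by 1255 that were 2-fold or more higher there in both groups. RNA degradation would raise the 3′ bias of Gapdh and Actb above that of the other 4 arrays, which FLX replicate 3 showed in 0 of 4 measures and VEH replicate 3 in 2, so it is argued against in the former and stays open in the latter. A lower share of all other cell types is argued against by oligodendrocyte markers, which were 1.15 or more higher in both groups. A smaller amount of leptomeningeal RNA was not tested apart from the list itself and stays open, and no biological explanation was tested, since the design names none for the replicate numbers.

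The 13 genes of the GABA and glycine receptor list were higher in FLX arrays. With any 1 array left out the list stayed higher with an adjusted p of at most 0.0433, but its median was 0.15 in place of 0.47 without VEH replicate 3, and the ribosomal list kept its call (adjusted p at most 0.0249) at -0.03 in place of -0.23 without FLX replicate 3, so dependence of either size on 1 array stays open. The profile that sets replicate 3 apart stays open for either list taken alone, this one or the 41 ribosomal protein genes. FLX and VEH arrays of pairs 1 and 2 differed on the first principal component by 25.1 and 4.84. That is less than the 28.2 between replicates of a group, so no sign is predicted. In those pairs the treatment difference had the sign of the replicate 3 difference in 1 of 13 and in 38 of 41 members, and without both replicate 3 arrays the medians were 0.33 and -0.13. Both lists were lower in replicate 3 (medians -0.97 and -0.32), so a shift along that profile would move both the same way. The opposite directions argue against it as the cause of both lists together. A difference in RNA integrity also stays open for either list and for the astrocyte markers, since it goes with treatment. The 3′ to 5′ difference, which rises as integrity falls, was lower in FLX arrays in 3 of 3 pairs. An effect of fluoxetine stays open as well. All 3 calls were lost with camera at an estimated correlation (adjusted p = 0.791), where few residual degrees of freedom let a lost call decide little.

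Astrocyte markers were higher in FLX arrays, and more astrocyte RNA in all FLX arrays should raise the most abundant ones. The 5 most abundant, Clu, Gja1, Apoe, Slc1a2 and Gjb6, had a median log2 difference of -0.0427, with 2 of them positive, which met the bound set beforehand against this explanation. It lay below the median of the list, 0.31, by more than the SD of the 5, 0.24. But Clu, Gja1, Apoe and Gjb6 were themselves lower in replicate 3 (-1.40, -2.16, -3.06 and -3.85). Slc1a2, at -0.67 there, had a treatment difference of 0.37. The 5 thus do not measure astrocyte RNA apart from the replicate 3 profile, and more astrocyte RNA in all FLX arrays stays open. The 8 markers below -1 in replicate 3 had a median of -0.02 with 3 positive, while the other 13 were all positive, from 0.24 to 1.5. Leaving out FLX replicate 2, VEH replicate 1 or VEH replicate 3 ended the call, with an adjusted p of up to 0.715. The medians were then 0.20, 0.30 and 0.18, so dependence on 1 array stays open. An effect of fluoxetine within astrocytes stays open as untested.

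Among the 10 splits of the 6 arrays into 3 and 3, which are too few for a share under 0.05, 10 gave as many changed probe sets as the real split, since it had 0 and the highest other 0. For the count at 1.5-fold 6 splits reached the real 61, and the highest other, FLX 1, FLX 3 and VEH 3 against the rest, had 6109, which points to a structure of the samples set by replicate 3. For lists called 7 splits reached the real 9, and the highest other had 18. Only 4 splits part all pairs of equal number, and the others of these exchange the treatments within 1 pair. With the block the real split had 677 probe sets at 1.5-fold against 175 to 354, 16 lists against 8 to 11, and a smallest adjusted p of 0.574 against 0.969 to 0.999. These 4 splits are also too few for a share under 0.05, so the ordering decides nothing about treatment.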
